A study of Rattus norvegicus with 4 samples.

How the data were processed

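Total RNA from blocks of hypothalamus (bregma -2.12 to -4.52 mm) of 8 male Sprague Dawley rats was hybridised to 4 two-colour Agilent rat arrays, per the labels. Each array held RNA of 1 rat injected with triiodothyronine (T3, the active thyroid hormone) in one dye and of 1 saline-injected rat in the other. T3 was in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4. The labels gave 4 replicates per treatment and 8 rats, so each array was taken as 1 independent pair of rats. All arrays lay on a single slide and were scanned together, so no slide or scan batch could be tested.

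The deposited scanner files held spot and background brightness as intensity values (median pixel brightness per spot, not normalized), made with Agilent Feature Extraction 10.7.3.1 per the file headers. The same files held processed intensity values (background-subtracted and dye-normalized by the scanner software) and a log10 ratio of Cy5 over Cy3, per the file headers. The authors' deposited value table of 41105 rows held log ratios taken here as log2, made with limma 3.18.9 per the submitters' processing notes. Its log base, centring and normalization steps were not given in the sources used here. Its columns had medians of 0.0026, -0.0024, 0.0021 and 0.0030 for arrays 1 to 4. Its ratios were read as T3 over saline because the spike-in control probes changed sign with the dye orientation. The array design was annotated on genome build rn4, per the file headers.

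The design had assumed mean spot signals, but the files held median signals, which were used in their place. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and each array was normalized by loess with control spots at weight 0. Control spots and spots marked as outliers by the scanner software were left out, and spots of a probe were averaged. Ratios on arrays with T3 in Cy3 were turned, so that every value was log2 of T3 over saline. A probe was kept when it was well above background on at least 3 of the 4 arrays in the T3 channel or in the saline channel, which left 23183 of 41012 probes. On arrays 1 to 4, 68.3%, 58.3%, 59.7% and 51.0% of spots were well above background in the T3 channel and 58.9%, 63.6%, 52.4% and 58.3% in the saline channel. The number of arrays limits the precision.

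Probes carried an accession and no gene name. Accessions were matched without versions to a RefSeq gene table of assembly GRCr8, used for names alone, and 16964 probes had 1 symbol while 24048 had none. The kept probes named 9302 genes, and a gene's value was that of its brightest kept probe. Coordinates were not used here.

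Differences were tested with limma (lmFit and eBayes, 2-sided) with a Benjamini-Hochberg adjusted p threshold of 0.05 over all kept probes. The fit had 3 residual degrees of freedom and 4.36 prior ones. For each of 26 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 and with an estimated correlation, together with fry. Fry values are those of its directional test unless its test for changes in either direction is named. Members without a value on an array in use were left out of camera, fry and the list means and medians, which left 10 of 11 measured genes raised by thyroid hormone, 28 of 30 neuropeptides, 15 of 16 interferon-responsive, 25 of 27 oxidative phosphorylation, 21 of 23 cholesterol, 18 of 19 fatty acid, 15 of 16 unfolded protein response and 11 of 12 neuronal genes. All measured members were counted over all probes and adjusted over the list alone. Errors are standard deviations over the 4 arrays. Arrays were simulated with the real brightness and limma's moderated spread over 23183 probes for T3 over saline. On these, 42 of 100 probes with a true log2 difference of 0.5 and 100 of 100 with a difference of 1 were called, with 3 false calls. The mean estimated sizes were 0.44 and 0.90. The noise was independent between arrays, with no dye effect of single probes and the same response on every array. These rates may therefore not carry over to the real arrays. In a simulation of 20 lists, the 1 shifted list was called and 0 of the others were. These lists were drawn at random from probes with independent noise, and the run was set to stop if the shifted list was missed. The simulation therefore cannot show how camera performs on lists whose members are correlated.

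Genes were named by a rule fixed before the data were examined. It took the 12 genes past the threshold with the highest and the 12 with the lowest log2 ratio, given the same sign on all 4 arrays. Where fewer than 6 passed in a direction, those with the smallest p up to 6 were added as not past the threshold. Of each list it took up to 4 members with the smallest p past 0.05 over all probes or over the list alone, and otherwise the member with the smallest p. It always took Hr, Klf9, Dio2, Dio3, Trh, Thra, Thrb and Nrgn, and a further gene of the rule is not reported here.

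Alternatives were no background subtraction, Agilent's processed signals, a normexp offset of 16, median centring, Aquantile scaling, no filter and a strict filter on dim probes, outlier spots kept, a dye term, eBayes with trend and robust, array weights, the authors' processed values, each replicate left out, an adjusted p threshold of 0.1, the mean of a gene's probes, and an estimated correlation in camera. The set of kept probes stayed fixed when a replicate was left out. Aquantile scaling changes brightness and not ratios, so it could move no fit. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.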

Results

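Gene expression was measured in the hypothalamus of 8 male rats. They were made hypothyroid by drinking 0.025% methimazole, an inhibitor of thyroid hormone synthesis, over 22 days. T3 (25 µg per 100 g) was injected into 4 of them on day 21 and saline into the other 4, and tissue was collected after 24 hours. The rats were 7 weeks old at the start and 10 weeks old at collection. The comparison asks which hypothalamic transcripts differed after T3 replacement. It rests on 4 arrays, each pairing a T3 rat with a saline rat, and on 23183 probes that named 9302 genes. Median spot brightness was 110 to 138.5 in Cy3 and 238 to 281 in Cy5, over backgrounds of 49 to 52 and 101 to 104.

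After T3, the transcripts of 14 genes were higher and 1 was lower (limma, adjusted p under 0.05). Hr, a nuclear corepressor and a known direct target of thyroid hormone, was 2.26-fold higher after T3 (log2 1.18 ± 0.15, SD, n = 4 arrays; limma adjusted p = 0.0129). Hhatl was 3.00-fold higher (1.58 ± 0.30) and Arc, an immediate early gene of neuronal activity, was 2.68-fold higher (1.42 ± 0.28), both with a limma adjusted p of 0.0129. Cbs, the enzyme that condenses homocysteine with serine, was the gene that fell, by 0.62 on the log2 scale (SD 0.10, limma adjusted p = 0.0426). All 23 probes past the threshold, 22 higher and 1 lower, had 1 sign on all 4 arrays.

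The highest ratio among genes past the threshold belonged to Bpifa1, a secreted epithelial protein, at 1.67 ± 0.54 on the log2 scale. Tnfsf13 and Tnfrsf9, a ligand and a receptor of the tumour necrosis factor families, rose by 1.28 ± 0.34 and 1.25 ± 0.23. Apoa4, an apolipoprotein, rose by 1.25 ± 0.38 and Gli2, a transcription factor of hedgehog signalling, by 1.24 ± 0.37. Cyp26b1, which degrades retinoic acid, rose by 1.10 ± 0.26. Defa24, a defensin of a family with near-identical members whose probe may bind several of them, rose by 0.99 ± 0.23. Acsl6, a long-chain acyl-CoA synthetase of brain, rose by 0.91 ± 0.14 and Apln, which encodes the peptide apelin, by 0.83 ± 0.06, while a dimmer Apln probe gave 0.66 without passing (limma adjusted p = 0.0563). Limma adjusted p for the genes of this paragraph lay between 0.0129 and 0.0341. In the saline channel, Hr, Tnfrsf9 and Apoa4 were well above background on 3 of 4 arrays and Defa24 on 1, so that the Defa24 ratio rests on a saline signal near background.

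Klf9, a transcription factor induced by thyroid hormone, lay at the threshold. Its brightest probe gave 0.90 ± 0.27 (limma adjusted p = 0.0517) and its other probe gave 1.09 (limma adjusted p = 0.0129). Dio3, the deiodinase that inactivates T3, had the highest mean ratio of the named genes, 2.49 ± 1.16, without passing (limma adjusted p = 0.0837). Its log2 ratios were 3.43 and 3.56 on the arrays with T3 in Cy5 and 1.59 and 1.40 on those with T3 in Cy3. With a dye term in the limma fit its adjusted p was 7.4e-04.

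On the lower side, 5 further genes did not pass. Mt2A, a metallothionein, was at -0.50 ± 0.06, and Qdpr, which regenerates tetrahydrobiopterin, at -0.59 ± 0.17. C19h1orf198 was at -0.56 ± 0.14, Slc25a34, a mitochondrial carrier, at -0.68 ± 0.27, and Cyp4f4, a cytochrome P450, at -0.80 ± 0.32. Their limma adjusted p lay between 0.0692 and 0.0931.

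**Figure D1:**
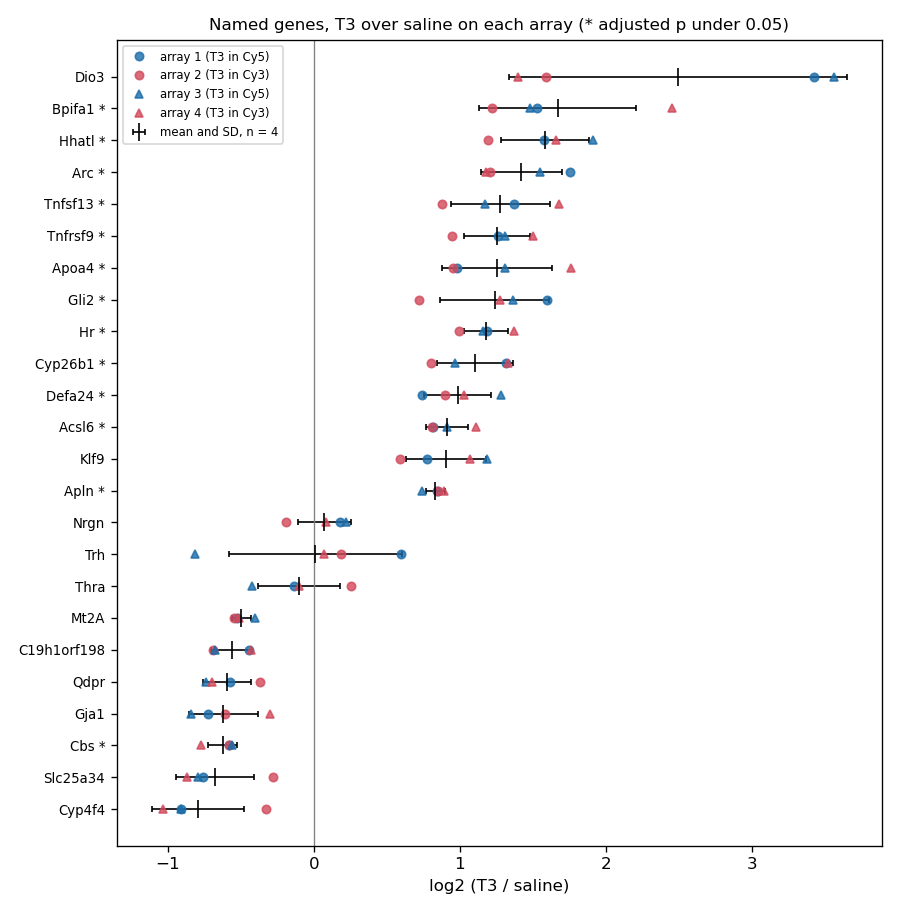
Log2 ratio of T3 over saline (horizontal axis) of named genes on each of the 4 arrays, coloured by dye orientation, with the mean and SD as black bars. Hr, Hhatl and Arc lie above 0 on all 4 arrays, and the Dio3 points split by dye orientation, at 3.43 and 3.56 against 1.59 and 1.40.

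Without replicate 1, 3 or 4, limma called 0 probes (1403, 1383 and 1577 at an unadjusted p under 0.05, against 1881 with all arrays), while without replicate 2 it called 60 higher and 8 lower, with 21 of the 23 probes among them. Agilent's processed signals and median centring also gave 0 calls (1948 and 132 at an unadjusted p under 0.05), and every one of the 23 probes kept its direction in each alternative that tested it. Because the 23 probes had 1 sign on all 4 arrays, leaving out a replicate or weighting arrays could not turn them. Aquantile scaling, the filters on dim probes, the dye term, eBayes with trend and robust and the threshold of 0.1 could not either, as they left these ratios unchanged.

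Of the list of genes known to be raised by thyroid hormone in brain, all 11 measured members had a higher mean after T3, with Hr past the threshold over all probes and 5 members past it adjusted over the list alone. Beside Hr, Klf9 and Dio3, these were Abcd2, a peroxisomal fatty acid transporter (0.42 ± 0.12), and Dbp, a clock output factor (0.33 ± 0.13). Camera placed the list above other genes (adjusted p = 5.1e-09, and adjusted p = 0.59 with an estimated correlation), and fry gave an adjusted p of 0.060. The list mean was 0.60 and its median 0.28, with Dio3 the highest member, and with the authors' processed values the mean and median were both 0.58 (camera adjusted p = 1.2e-08). Nrgn, a postsynaptic calmodulin-binding protein also on the list, was at 0.07 ± 0.18 (limma adjusted p = 0.93).

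Genes known to be lowered by T3 did not shift as a list (4 measured, 2 with a lower mean, camera adjusted p = 0.63). Trh, the releasing hormone of the thyroid axis, was at 0.01 ± 0.59, with values of 0.60, 0.18, -0.81 and 0.07 on arrays 1 to 4. The blocks spanned bregma -2.12 to -4.52 mm, and which Trh neurons they held was not measured. The Trh value therefore does not show how T3 acted on the Trh neurons of the thyroid axis. Pcsk2, a prohormone convertase, was at -0.11 ± 0.17. Of 15 measured genes of thyroid hormone metabolism, transport and receptors, Hr passed over all probes, and Hr, Dio3 and Rxrg passed adjusted over the list alone (camera adjusted p = 0.17). Rxrg, a retinoid X receptor, was lower (-0.39 ± 0.21), and the receptor gene Thra was at -0.10 ± 0.28. The probe of Dio2 was well above background on too few arrays to be tested, and no probe was matched to Thrb.

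By camera with the preset correlation, feeding and releasing-hormone neuropeptides were shifted down as a list, with no single member past the threshold. A lower mean was seen for 24 of 30 measured members (camera adjusted p = 1.0e-04, and adjusted p = 0.59 with an estimated correlation). Fry gave an adjusted p of 0.45. Penk, the enkephalin precursor, had the smallest p (-0.39 ± 0.16, limma adjusted p = 0.20). The list mean of -0.15 had an SD of 0.25 over the 4 arrays. It was -0.026 without replicate 3 (camera adjusted p = 0.26) and -0.054 with the authors' processed values, where the median was 0.0096 (camera adjusted p = 0.21). On array 3 the median of the hypothalamic nucleus markers was -0.18, against 0.018, 0.027 and 0.0017 on arrays 1, 2 and 4. Avp and Oxt of the list, the precursors of vasopressin and oxytocin, were chosen after their values were seen. They were at -2.63 and -2.53 on array 3, against -0.72 to 1.81 on the others. In the authors' processed values they were at 0.53 and 0.15 on array 3 and lowest on array 4, at -2.06 and -1.35. The choroid plexus markers Ttr and Sostdc1, chosen likewise, were at 3.53 and 2.70 on array 3, against -0.37 to 0.45 on the others. Their processed values on array 3 were 3.48 and 1.11.

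Immediate early genes were shifted up by camera with the preset correlation, and 10 of 13 measured members were higher (camera adjusted p = 0.0017, and adjusted p = 0.59 with an estimated correlation). The fry adjusted p was 0.29. Arc passed over all probes, and Gadd45b, a stress-induced regulator, passed adjusted over the list alone (0.36 ± 0.16). With the authors' processed values the list was not called (camera adjusted p = 0.34).

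Interferon-responsive genes were shifted down by camera with the preset correlation, and 13 of 16 were lower (camera adjusted p = 0.0017, and adjusted p = 0.59 with an estimated correlation). By fry the adjusted p was 0.45. Irf7, a regulator of interferon transcription (-0.43 ± 0.23), and Psmb9, an immunoproteasome subunit (-0.38 ± 0.18), passed adjusted over the list alone. The list mean of -0.15 had an SD of 0.27 over the 4 arrays. By array, the list median was 0.17 on array 4 and -0.29 to -0.20 on arrays 1 to 3. The list mean was -0.086, -0.095 and -0.28 without replicate 2, 3 or 4, and the median of -0.18 was -0.29, -0.088 and -0.26. With the authors' processed values the mean was -0.064 (camera adjusted p = 0.27).

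Oligodendrocyte and myelin markers were lower in 13 of 18 members (camera adjusted p = 0.012, and adjusted p = 0.59 with an estimated correlation), and fry gave an adjusted p of 0.45. Opalin, a myelin membrane protein, had the smallest p (-0.47 ± 0.31, limma adjusted p = 0.28), and its other probe gave -0.18. The list median was 0.10 on array 4 and -0.32 to -0.12 on arrays 1 to 3. The list mean of -0.12 had an SD of 0.15 over the 4 arrays. It was -0.11, -0.057, -0.13 and -0.17 without replicates 1 to 4 (camera adjusted p = 0.047, 0.18, 0.019 and 4.9e-05). With the authors' processed values the mean was -0.17 (camera adjusted p = 0.0030, and adjusted p = 0.31 with an estimated correlation). On array 2, Hbb-b1, a haemoglobin subunit of red blood cells chosen after its value was seen, was at -4.25, against 0.062 to 1.87 on the others. A link to the myelin markers was not tested.

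In the retinoic acid pathway (9 measured), Cyp26b1 passed over all probes, and Aldh1a1, which makes retinoic acid, passed adjusted over the list alone (0.54 ± 0.37, camera adjusted p for the list = 0.12). Of 27 oxidative phosphorylation genes, 25 had a higher mean with 0 past the threshold (camera adjusted p = 0.064), and Cycs, cytochrome c, was at 0.26 ± 0.08. Of 16 unfolded protein response genes 12 were higher (camera adjusted p = 0.055), among them Dnajb11 at 0.21 ± 0.06. Of 19 genes of fatty acid synthesis and AMPK 0 passed (camera adjusted p = 0.25), and Fads1, a desaturase, was at 0.44 ± 0.26. Of 23 cholesterol genes 0 passed (camera adjusted p = 0.80), and Srebf2, their main transcription factor, was at -0.11 ± 0.11 and at 0.023 by its other probe. Among 13 clock genes Dbp passed adjusted over the list alone (camera adjusted p = 0.44). Among 11 glucocorticoid-responsive genes Mt2A did so on the lower side (camera adjusted p = 0.33). Of 23 energy balance receptors 0 passed (camera adjusted p = 0.65), and Calcr, the calcitonin receptor, was at -0.27 ± 0.17.

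Cell type markers went both ways, and camera tests for a shift of a list in 1 direction. Fry's test for changes in either direction gave an adjusted p of 0.039 for astrocyte, 0.0095 for endothelial and mural and 0.0050 for ependymal markers. It was 0.066 for tanycyte, 0.89 for microglia, 0.69 for neuronal and 0.52 for hypothalamic nucleus markers. Among 14 astrocyte markers Gja1, a gap junction protein, was lower (-0.62 ± 0.23) and Fgfr3 higher (0.34 ± 0.20), both adjusted over the list alone (camera adjusted p = 0.64). Among 15 endothelial and mural markers Cldn5, a tight junction protein, was lower (-0.37 ± 0.07) and Tie1, a receptor kinase, higher (0.34 ± 0.15), again adjusted over the list alone (camera adjusted p = 0.62). Of 10 ependymal markers the cilium genes Tekt1 (-0.29 ± 0.15), Tekt4 (-0.28 ± 0.21) and Spef2 (-0.21 ± 0.09) were lower, adjusted over the list alone. Pltp, a phospholipid transfer protein (0.21 ± 0.09), and Mia, named after its value was seen (0.21), were higher in the same count (camera adjusted p = 0.25). Adm in the 10 tanycyte markers was at 0.53 ± 0.37 (camera adjusted p = 0.44), P2ry12 in the 16 microglia markers at -0.14 ± 0.21 (0.64) and Elavl4 in the 12 neuronal markers at 0.15 ± 0.16 (0.64). Hdc, the histamine-synthesizing enzyme among the 11 hypothalamic nucleus markers, was at -0.31 ± 0.21 (camera adjusted p = 0.33).

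Blood, meninges and choroid plexus markers varied between arrays by more than their mean T3 difference, as did the neuropeptide, interferon-responsive and oligodendrocyte lists. The mean ratio of the 10 blood and meninges markers was 0.010 with an SD of 0.86 over the 4 arrays (camera adjusted p = 0.61) and that of the 8 choroid plexus markers 0.18 with an SD of 0.53 (camera adjusted p = 0.86). Array 2 moved the first mean the most, with Hbb-b1, Hbb and Alas2, genes of red blood cells chosen after their values were seen, at -4.25, -3.25 and -3.20 there and above 0 on the other arrays. Without replicate 2 it was 0.41 (camera adjusted p = 7.4e-04, and adjusted p = 0.64 with an estimated correlation). The choroid plexus mean was -0.053 without replicate 3 (camera adjusted p = 0.27), the array with the high Ttr and Sostdc1 ratios, and 0.37 without replicate 2 (camera adjusted p = 0.18). Igfbp2 of the blood and meninges markers was at 0.25 ± 0.42 and Calml4 of the choroid plexus markers at -0.33 ± 0.24. Tshb, the beta subunit of thyrotropin, was lower among 5 pituitary markers adjusted over the list alone (-0.67 ± 0.57, lower on 3 of 4 arrays and well above background on 2 of 4 in the T3 channel, camera adjusted p for the list = 0.21). Prkcd among 8 thalamus markers was at 0.20 ± 0.33 (camera adjusted p = 0.44). The mean, median and test direction differed in sign for the cholesterol, clock, energy balance and microglia lists, all without a call.

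**Figure D2:**
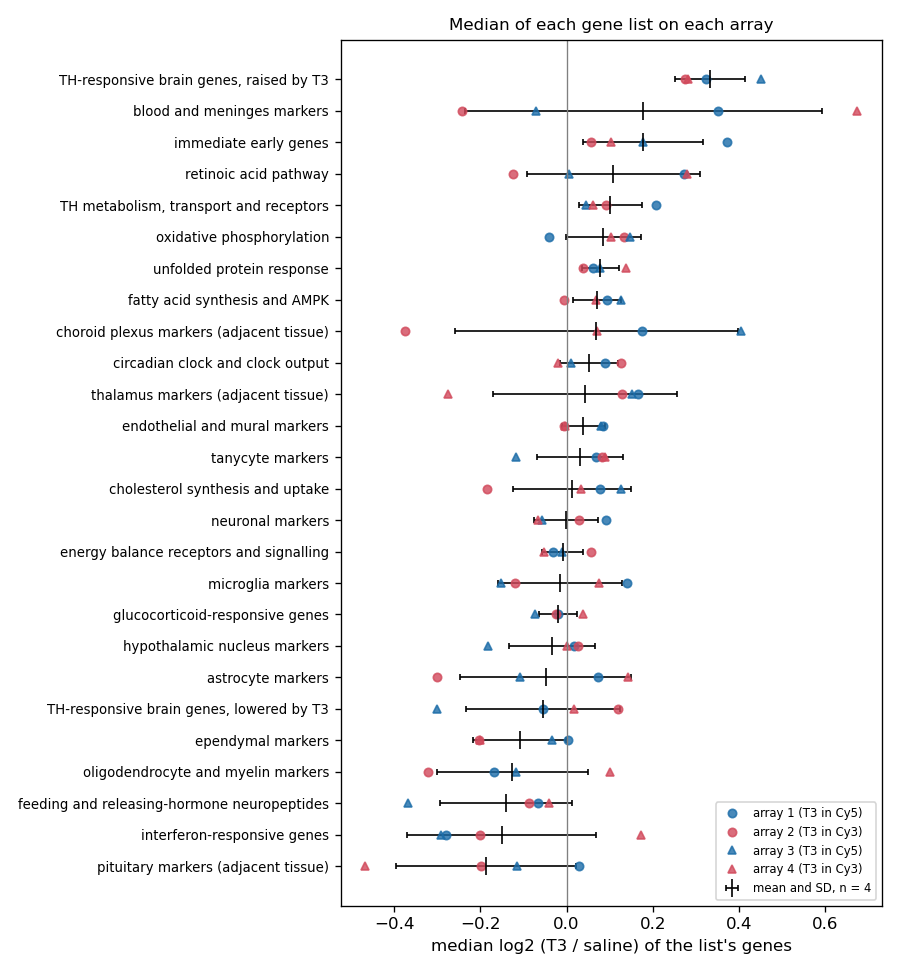
Median log2 ratio of T3 over saline (horizontal axis) of each gene list on each of the 4 arrays, coloured by dye orientation, with the mean of the 4 medians and their SD as black bars. The list of genes raised by thyroid hormone lies above 0 on every array, while blood, choroid plexus and thalamus markers lie on both sides of 0.

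Across the 9302 genes, which are not independent replicates, Pearson r was 0.42 for arrays 1 and 3 and 0.22 for arrays 2 and 4, the pairs of the same dye orientation. It was -0.11 to 0.22 for the pairs of opposite orientation. Limma with a dye term called 0 probes for a dye effect and 15 probes for T3, all higher. At an unadjusted p under 0.05 there were 3938 probes for the dye and 2902 for T3, where chance gives about 1159. The SD over probes was 0.144 for the dye coefficient and 0.143 for the T3 coefficient, so the lack of calls does not show that dye effects were absent.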

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

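The tests on array 2 and on the dye bias of Dio3 were chosen after the results were seen; the exchange of rats within pairs was planned, but what it should show was written down after its counts were seen. A value on 1 array lay far from the other 3 in 6 of 80 genes and lists tested, where chance gives about 1 in 20, or 4. Fads1 was at 0.055 on array 2 against 0.54 to 0.59 on the others (gap over range 0.912). Cbs was at -0.77 on array 4 against -0.59 to -0.56 (0.879). The thalamus markers had a median of -0.28 on array 4 against 0.13 to 0.17 (0.917). Array 3 stood apart in 3 lists, all lower there: feeding and releasing-hormone neuropeptides (-0.37 against -0.087 to -0.040, 0.855), hypothalamic nucleus markers (-0.18 against 0.0017 to 0.027, 0.877) and tanycyte markers (-0.12 against 0.069 to 0.090, 0.897).

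Over the 100 probes with the smallest p on the other 3 arrays, ratios in the scanner files were smaller on array 2. Its slope on the mean of those arrays was 0.39 (95% bootstrap interval over probes 0.30 to 0.47), while arrays 1, 3 and 4 had slopes of 0.93, 0.83 and 0.84 obtained the same way. Over all kept probes the SD of the ratios was 0.24 on array 2, against 0.27, 0.25 and 0.23 on arrays 1, 3 and 4. Ratios compressed on array 2 are argued against by the spike-in controls, whose slope there was 1.04. A smaller response whenever T3 is in Cy3, of the size seen on array 2, is argued against by array 4, in the same orientation, at 0.843. The reference for array 4 included the smaller ratios of array 2, which raises that slope, so a lesser effect of the orientation stays open. In the authors' processed values, over the same kind of probes, array 2 had a slope of 0.99, against 0.77, 0.68 and 1.03 for arrays 1, 3 and 4, so the pattern was absent there, though those values were only loosely related to the scanner ratios. Array 2 was also the outlier for red blood cell genes, with Hbb-b1, Hbb and Alas2, chosen after their values were seen, at -4.25, -3.25 and -3.20 against 0.062 to 1.87 on the others (-1.08 to -0.68 against -0.40 to 2.34 in the authors' processed values); blood content was not tested as an explanation, what makes the ratios smaller stays open, and no biological explanation was tested.

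The Dio3 ratio followed the dye orientation, with means of 3.49 for T3 in Cy5 and 1.49 for T3 in Cy3. The loess step used here is argued against as the source by a gap of 2.97 with median centring, which uses no loess. The gap was 2.45 with Agilent's processed signals, which carry the scanner software's own dye normalization. A dye bias of the probe had a dye coefficient of 1.00 (limma with a dye term, unadjusted p = 6.2e-06, adjusted p = 0.095), yet in the authors' processed values the gap was -1.32, the other way, so the tables conflict and a dye bias stays open. The mean over both orientations cancels such a bias, and a difference between the rats stays open, untested.

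For the 23 probes past the threshold, the 8 ways of exchanging the rats within pairs are too few for a share under 0.05: the real arrangement gave 23 and 1 of the 8 reached that count, while the highest of the others gave 2.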

How the results depend on the processing

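All alternatives were planned before the data were examined, and the cause of a change was not tested unless stated. Probes higher and lower, 22 and 1 as reported, became 0 and 0 with Agilent's processed signals and with median centring, 14 and 0 with a normexp offset of 16, 59 and 8 with no filter on dim probes, 15 and 0 with a dye term, 36 and 2 with eBayes trend and robust, 10 and 0 with the authors' processed values, and 79 and 11 at an adjusted p under 0.1. Genes higher and lower, 14 and 1 as reported, became 0 and 0 with Agilent's processed signals and with median centring, 9 and 0 with offset 16, 35 and 5 with no filter, 8 and 0 with the dye term, 6 and 0 with the authors' processed values, 45 and 8 at 0.1, and 34 and 4 with the mean of a gene's probes, which also adjusts over genes in place of probes. Leaving out 1 replicate gave 0 to 60 probes higher, 0 to 8 lower, 0 to 42 genes higher, 0 to 3 lower and 6 to 7 lists. Of the lists not shifted with all arrays, camera called oxidative phosphorylation and pituitary markers without replicate 1, the retinoic acid pathway without 2 or 3, blood and meninges markers without 2, the unfolded protein response without 3 and thalamus markers without 4, each with an adjusted p of 0.56 or more with an estimated correlation. The 5 shifted lists became 0 with an estimated correlation in camera, where the estimates for them ran from 0.16 to 0.30. None of the 5 had an adjusted p under 0.05 in fry's directional test. In fry's test for changes in either direction, the adjusted p was 0.0050 for genes raised by thyroid hormone and 0.0119 for immediate early genes. It was 0.66 for neuropeptides, 0.11 for interferon-responsive genes and 0.066 for oligodendrocyte markers. That test does not ask whether a list shifted in 1 direction. The mean r between arrays moved with median centring from 0.32 to 0.59 within a dye orientation and from 0.064 to -0.42 between orientations. The 13 named genes past the threshold kept their direction in 230 of 230 alternatives and stayed past it in 144. Part of both counts was fixed in advance. The genes were chosen for the same sign on all 4 arrays, so that leaving out a replicate or weighting arrays could not turn them. Aquantile scaling and the threshold of 0.1 could change no direction and lose no call. The dye term and eBayes with trend and robust left the mean ratios of these genes unchanged, so they could lose calls but turn no gene. The filters on dim probes changed no ratio of a probe. Of the genes not past it, Trh turned to -0.045 with Agilent's processed signals, -0.044 with median centring, -0.027 with array weights and -0.22 with the authors' processed values, and ranged from -0.19 to 0.28 with 1 replicate left out (-0.048 and -0.011 without replicate 2 or 4). Thra turned to 0.0055 without replicate 3. With the authors' processed values Thra was at 0.0090, Pcsk2 at 0.12, Penk at 0.17, Prkcd at -0.37 and Elavl4 at -0.0052. Of the 23 called probes, 12 were called with the dye term and 6 with the authors' processed values. Signal over background limits what was measured: 17829 of 41012 probes were not kept.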

Other observations

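Several genes outside the naming rule, chosen after their values were seen, lay past or near the threshold. Foxa2, a forkhead transcription factor, rose by 0.66 (limma adjusted p = 0.0426) and Slc25a33, a mitochondrial pyrimidine nucleotide carrier, by 0.75 (limma adjusted p = 0.0426). Th, the rate-limiting enzyme of dopamine synthesis, was at 0.59 and higher on 4 of 4 arrays without passing (limma adjusted p = 0.0563). Engase was past the threshold by 1 probe (1.29, limma adjusted p = 0.0322) and not by its brighter one (0.57, limma adjusted p = 0.12). Klf10, of the same family as Klf9, was at 0.61 (limma adjusted p = 0.093). Prodh, an enzyme of proline catabolism, was at 0.53 (limma adjusted p = 0.0692). A further 6 probes past the threshold had no gene symbol here.

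The authors' processed values and the scanner ratios were only loosely related (Spearman rho 0.37, 0.39, 0.14 and 0.22 for arrays 1 to 4 over the kept probes, which are not independent replicates), although all 23 called probes had the same direction in both. Within the processed values, the columns of arrays 3 and 4 had a Pearson r of -0.51 over the kept probes, though both were read as T3 over saline. The SDs of these columns were 0.45 and 0.39, against 0.24 and 0.25 for arrays 1 and 2. The processed values are therefore a limited check on the scanner ratios. The tests on probe names and columns were chosen after the results were seen. A dye curve left in the processed values is argued against, because at most 0.28% of a column's variance lay on such a curve and the lowest rho was 0.141 after its removal. Names out of step with values are argued against by the 10 spike-in probes, with a lowest r of 0.991. Exchanged columns are argued against within a dye orientation by a mean r of at most 0.254, against 0.331 as labelled, and between orientations by the spike-in probes, whose r was -0.989 or lower. The source of the difference stays open, and no biological explanation was tested.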
